A study of Homo sapiens with 11 samples.

How the data were processed

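RNA of MDA-MB-231 cells was measured on 11 Affymetrix HG-U133 Plus 2.0 arrays in 9 groups, per the labels: 2 control arrays, 2 E2-BSA arrays and 1 array each for ethanol, estradiol, ICI, G15, E2-BSA with ICI, E2-BSA with G15, and BSA. Per the labels' protocols, the cells were grown in RPMI medium, preincubated for 4 h in charcoal-stripped serum and treated for 3 h, RNA was isolated with a column kit, and labelling and hybridisation followed the Affymetrix protocol. The series title mentions a time course, but all 11 arrays are of 3 h.

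The deposited values were analysed as log2 values centred per probe set. The labels do not state how the authors summarised or normalised the arrays, nor the log base, which was taken as 2. The values range from -4.20 to 6.69. In 28064 of the 54675 probe sets (51.3%) the 2 values nearest 0 mirror each other within 1e-05, with up to 8 values on the same side, which is what subtracting a median over an even set of at least 16 arrays leaves. No absolute level and no signal over background can therefore be given. The medians of all probe sets were -0.01 and -0.05 in the control arrays, -0.01 for ethanol, -0.02 for estradiol, -0.0030 and -0.02 for E2-BSA, 0.06 for ICI, 0.06 for G15, 0.06 for E2-BSA with ICI, -0.01 for E2-BSA with G15 and 0.09 for BSA. Their range of 0.14 lay under the limit of 0.2 set before the data were examined, so no normalization between arrays was applied. The median gene differed from the second control array by 0.19 in the BSA, 0.16 in the ICI and 0.16 in the G15 array, a shift that the single-gene differences include and the list tests do not, since they compare a list with the other genes.

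Probe sets were joined to genes by the platform's annotation: 41091 had 1 gene symbol, 1801 had several, 11777 had none and 62 were Affymetrix controls. The gene ids of 41037 of the first were in the current gene table, and 0 symbols needed an update. Averaging gave 19775 genes, 10523 of them with more than 1 probe set. Comparisons, tests, 31 gene lists and the rule for naming genes were laid down before the data were examined. The centred values forced these departures: a gene's probe sets were averaged where the brightest had been intended, no dim genes were left out, no pseudocount was used, and random lists were matched on the number of probe sets per gene and not on level.

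Tests used limma 3.58.1 in R 4.3.3, with a trend in the prior variance and Benjamini-Hochberg adjustment over genes at 0.05. On these centred values the trend runs over a gene's mean centred value, which is not its intensity. Comparisons of single groups used a mean per group over all 11 arrays, with 2 residual degrees of freedom, all from the control and E2-BSA duplicates. A group with 1 array was assumed to vary like those. Comparisons with 1 array on a side have no replicate check. E2-BSA, ICI and G15 present against absent used an additive fit to 8 arrays with 4 residual degrees of freedom. The poly-A spike-in controls, 24 probe sets, parted the arrays into sets of 3 and 8, with a gap of 1.30 between the sets and a next largest gap of 0.39. The labels give no batch, and a term for these sets was added to each fit after the data were seen. That left 1 residual degree of freedom in the group means fit and 3 in the 8-array fit. An additive batch fit to all 11 arrays, with terms for each treatment and the set but no antagonist interaction, left 3. It was chosen on its simulated false calls before its own calls were seen, but after those of the other fits. In it, E2-BSA against control and E2-BSA present against absent are the same contrast, and neither test of an antagonist interaction can be made. After the data were seen, the splits of the 8 arrays were repeated with a term for the sets, and the interactions were recomputed within the set of 8 from single arrays.

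Each fit was tested on simulated data, 20 simulations of 19775 genes, with 200 genes changed or none, and with variances drawn from the fitted prior or from the moderated variances. On unchanged data the additive batch fit made a mean of at most 0.3 false calls and at most 3 in a simulation. The group means fit with a batch term made means of 18.6 (at most 81) for E2-BSA against control, 15.4 (at most 87) for BSA against control and 17.2 (at most 71) for the G15 interaction under moderated variances, and 0.2, 0.1 and 0.1 under the fitted prior. With 200 genes changed, 20.0%, 18.8% and 20.6% of its calls were false under moderated variances, so its counts are given beside the others but carry an error rate above the nominal 5%. The additive batch fit exceeded it as well under moderated variances, with 7.12% for E2-BSA against control and 7.25% for BSA against control, and had 5.13% and 4.55% under the fitted prior. For BSA against control the additive batch fit recovered 55.4% to 88.8% of changes of 1 and 97.95% to 99.9% of changes of 2, and the fit without a batch term 0.35% to 1.4% and 26.05% to 39.45%. For E2-BSA present against absent the fit without a batch term recovered 0 changes of either size, because it counts the difference between the sets as spread. There the additive batch fit recovered 95.5% to 99.9% of changes of 1 and 99.95% to 100% of changes of 2, each simulated in all arrays with E2-BSA. The simulations drew genes independently and gave a gene the same variance in all arrays. In the data, the SD over genes was 0.15 for the second E2-BSA minus the second control array. It was 0.23 for ethanol and 0.26 for BSA minus that control, and 0.29 for E2-BSA+G15 minus G15. False calls from a single array that departs as a whole were therefore not measured.

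The lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Genes passing when adjusted over the list alone were counted as well. List medians of single array pairs were placed among those of 10000 random lists. Correlations of effects across genes are descriptions without a p-value. For E2-BSA against control, E2-BSA present against absent and estradiol against ethanol, the naming rule took up to 12 higher and 12 lower genes with the largest change among those passing, in the first only where both treated arrays lay outside the range of both controls. It filled each side to 5 with the smallest unadjusted p, named as not passing. The other comparisons took up to 5 per side, filled to 2. The measured receptors and up to 4 members of a described list with the smallest p were added. The rule was applied in the fits with a batch term as well, and the text gives the additive batch fit where it called genes.

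Alternatives set before the data were examined were quantile normalization, no trend, no antagonist terms, the 4 control and E2-BSA arrays alone, their replicate number as a block, the BSA array among the arrays without E2-BSA or as the control of the E2-BSA effect, an estimated correlation, and leaving out in turn each control and E2-BSA array, or each of the 8 arrays in the fits to those. Added after the data were seen were the batch terms, median centring and every probe set tested singly. The 3 figures were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.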

Results

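MDA-MB-231 is an established human breast cancer cell line of the triple-negative type, which lacks appreciable estrogen receptor alpha. Transcripts were measured on 11 Affymetrix HG-U133 Plus 2.0 arrays, a platform on which several probe sets of short oligonucleotides can read the same gene. The cells were kept for 4 h in medium with charcoal-stripped serum and then treated for 3 h. Free estradiol was given at 1 µM, and so was E2-BSA, estradiol coupled to bovine serum albumin, a conjugate used to address receptors at the cell surface. ICI, an antagonist known here only by that abbreviation, and G15, an antagonist of the G protein-coupled estrogen receptor GPER, were given at 10 µM, alone or with E2-BSA. The carrier protein BSA (1 µM) and the vehicle ethanol (0.1%) had an array of their own. Control and E2-BSA had 2 arrays each, and the other 7 groups had 1 array each, so the number of arrays limits the precision. The labels did not say whether the duplicates came from separate cultures, so the p-values measured only the spread between these arrays. The values were relative to each probe set's own median, so differences between arrays could be given for 19775 genes but no level of a gene.

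The 11 arrays fell into sets of 3 and 8. The poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, averaged 1.62 in the first control array, 1.58 in the estradiol array and 1.40 in the first E2-BSA array, on the log2 scale and over 24 probe sets. In the other 8 arrays they averaged between -0.56 and 0.10. Many genes followed the same division. With the control and E2-BSA duplicates averaged within each set, 912 genes differed by more than 1 between the sets, 582 of them higher and 330 lower in the set of 3. The cytokine gene IL6 stood at 2.49 in the first control array and at -1.74 in the second. Each duplicated group had 1 array in either set, the estradiol array lay in the set of 3, and the ethanol, BSA and antagonist arrays all lay in the set of 8. Each comparison is therefore given by limma without a batch term, as laid down before the data were examined, and with a term for the set, chosen after the data were seen. An additive batch fit to all 11 arrays, without antagonist interactions, left 3 residual degrees of freedom.

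**Figure D1:**
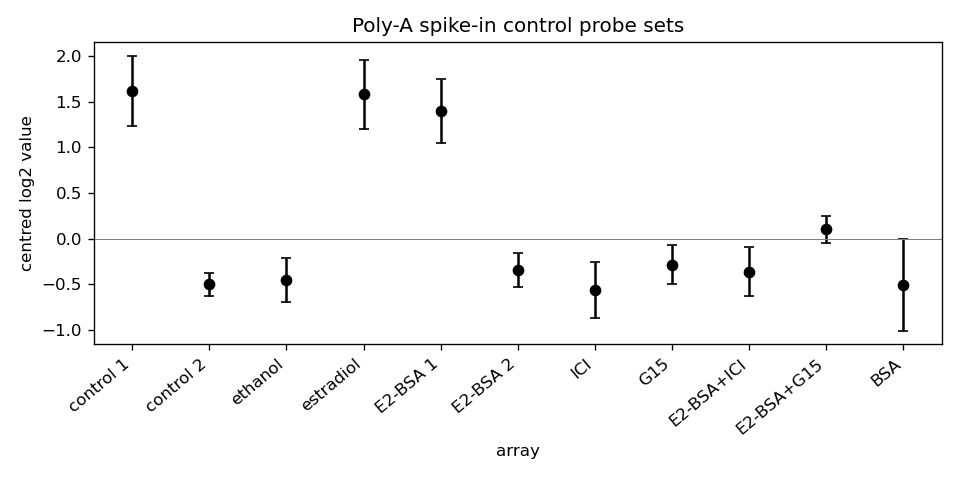
Mean centred log2 value of the 24 poly-A spike-in probe sets in each of the 11 arrays, with the SD over probe sets as bars. The first control, the estradiol and the first E2-BSA array lie between 1.40 and 1.62, and the other 8 between -0.56 and 0.10.

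E2-BSA was first set against the untreated control, with 2 arrays on each side. Canonical histone genes were lower with E2-BSA, by a mean log2 difference of -0.68 ± 0.49 (SD over genes), in 8 of 9 measured members. H2AC6 differed by -1.56 ± 0.47 (SE), H2BC5 by -0.76 ± 0.23 and H4C8 by -0.76 ± 0.27, none of which passed the test of single genes. Interferon-stimulated genes averaged -0.25 ± 0.18, and 2 of 28 were higher, with IRF9, a subunit of the interferon-activated transcription factor, at -0.29 ± 0.21 and the ubiquitin-like modifier ISG15 at -0.34 ± 0.28, which ranged from -0.70 to 0.022 with 1 of the 4 arrays left out. Camera called both lists lower (adjusted p = 6.9e-09 and 4.9e-04), and the calls were lost with an estimated correlation (adjusted p = 0.991 for either list). Both differences were unequal between the arrays: the median interferon gene differed by -0.48 between the first arrays of the groups and by 0.01 between the second, and the median histone gene by -1.06 and -0.33.

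No single gene passed between E2-BSA and control. Limma without a batch term called 0 genes, with 62 at an unadjusted p under 0.05. The fit with a batch term called 0 (1114 at that unadjusted level), and the additive batch fit called 0 (927). Of the genes with the smallest p without a batch term, none of which passed, RFPL3 was at 0.81 ± 0.20, SLC13A5, a citrate transporter of the plasma membrane, at 0.68 ± 0.17, the long noncoding RNA LINC00574 at 0.61 ± 0.16, the kinase DAPK3 at 0.60 ± 0.16 and LOC101927450 at 0.54 ± 0.15. On the lower side, SVIL-AS1 was at -0.80 ± 0.20, PPP1R14A, an inhibitor of myosin phosphatase, at -0.73 ± 0.21, EXOC3-AS1 at -0.65 ± 0.17, RPL23AP53 at -0.60 ± 0.16 and ZNF662 at -0.56 ± 0.16. Sterol synthesis and uptake genes averaged -0.10 (7 of 23 higher) and luminal epithelial markers -0.09 (5 of 20 higher), each called by camera (adjusted p = 0.0447). Neither call held with an estimated correlation (adjusted p = 0.991).

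Across antagonist backgrounds, E2-BSA was present in 4 arrays and absent from 4. The fit gives the mean difference over the backgrounds, so a response seen in only some of them can be called as well. NF-kB and inflammatory cytokine genes were higher with E2-BSA, by a mean of 0.17 ± 0.33 (SD over genes), in 23 of 31 measured members. TNFAIP3, which encodes an inhibitor of NF-kB signalling, was at 0.79 ± 0.53 (SE), NFKBIA, another such inhibitor, at 0.25 ± 0.21, IL11 at 0.40 ± 0.33 and TNF at 0.17 ± 0.14, none passing the test of single genes. The members were higher in 21, 24, 22 and 19 of 31 cases in the pairs of the first arrays, the second arrays, the ICI background and the G15 background. TNFAIP3 was higher in each of the 4 pairs, by 0.78, 0.53, 0.69 and 1.18, and the chemokine gene CXCL1, chosen after its values were seen, by 1.89, 0.78, 0.84 and 1.85. Camera called the list higher without a batch term (adjusted p = 0.0425, and 0.994 with an estimated correlation) and in the additive batch fit (adjusted p = 5.5e-07, and 0.237 with an estimated correlation). Of its members, 4 passed in the additive batch fit when adjusted over the list alone, and 0 over all genes or without a batch term.

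Sterol synthesis and uptake genes moved the other way, with a mean of -0.10 and 2 of 23 members higher in the presence of E2-BSA. Camera called them lower (adjusted p = 0.0253), which was lost with an estimated correlation (adjusted p = 0.786). Histone genes averaged -0.34 with 1 of 9 higher (adjusted p = 0.0253, and 0.994 with an estimated correlation), H2AC6 at -0.87 ± 0.37, H1-4 at -0.40 ± 0.23 and H1-2 at -0.49 ± 0.36. In the ICI and G15 backgrounds the median histone gene differed by 0.00 and 0.05. Members of the interferon list were IFI35 at -0.19 ± 0.11, XAF1 at -0.27 ± 0.19, HERC5 at -0.22 ± 0.18 and IFI44L at 0.18 ± 0.14. The additive batch fit called that list lower as well (mean -0.12, 6 of 28 higher, adjusted p = 0.0198), but not with an estimated correlation (adjusted p = 0.906). Its median was -0.48 in the pair of the first arrays, with 0 of 28 higher. It was 0.01 in that of the second arrays (15 of 28), -0.02 in the ICI background (13 of 28) and -0.02 in the G15 background (13 of 28).

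None of the measured steroid and estrogen-related receptors passed in this comparison. ESR1 was at 0.05 ± 0.09, ESR2 at 0.01 ± 0.09, GPER1 at -0.07 ± 0.15, PGR at -0.09 ± 0.13, NR3C1 at 0.03 ± 0.09, ESRRA at 0.07 ± 0.11 and ESRRG at -0.02 ± 0.14. The 27 measured classical estrogen-induced genes averaged -0.06, with 11 higher (camera adjusted p = 0.615), the 30 immediate early genes -0.01, with 14 higher (adjusted p = 0.985), and the 16 genes reported after GPER activation 0.05, with 10 higher (adjusted p = 0.563). Limma called 0 of 19775 genes without a batch term (208 at an unadjusted p under 0.05), 0 with one (924) and 0 in the additive batch fit (927). The smallest p belonged to CGREF1 (0.49 ± 0.12), SP7 (0.42 ± 0.11), TGM6 (0.41 ± 0.11), the leukotriene receptor gene CYSLTR2 (0.42 ± 0.11) and the neuromedin receptor gene NMUR1 (0.40 ± 0.11), and to SOCS2-AS1 (-0.58 ± 0.14), SMIM30 (-0.42 ± 0.10), the pseudogene HSD17B7P2 (-0.41 ± 0.11), C8G (-0.34 ± 0.09) and ZNF320 (-0.35 ± 0.10). Over all genes, 2656 (13.4%) differed in the same direction in all 4 pairs, where chance gives 12.5%.

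The carrier protein was set against the control to measure what BSA does without the hormone. The BSA array had the largest differences of the NF-kB and inflammatory cytokine genes: in the additive batch fit the list averaged 1.47 ± 1.33 (SD over genes) and 31 of 31 measured members were higher. The neutrophil-attracting chemokine genes CXCL1 and CXCL3 rose by 5.90 ± 0.42 (SE, adjusted p = 0.00383) and 4.03 ± 0.32 (adjusted p = 0.00435). TNFAIP3 rose by 2.99 ± 0.20 (adjusted p = 0.00295), IL6 by 2.71 ± 0.14 (adjusted p = 0.00113) and EFNA1, an ephrin ligand, by 2.21 ± 0.19 (adjusted p = 0.00457). Of the list, 13 members passed over all genes and 19 when adjusted over the list alone. Camera called it higher (adjusted p = 2.3e-24), and this was the single camera call of all comparisons and fits that held with an estimated correlation (adjusted p = 0.0386).

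Lower in the BSA array were ZNF266, which fell by 2.34 ± 0.14 (adjusted p = 0.0022), GPR137B, a lysosomal membrane protein, by a log2 difference of -2.01 ± 0.15 (adjusted p = 0.00399), PPP1R15B, a regulatory subunit of an initiation factor phosphatase, at -1.97 ± 0.17 (adjusted p = 0.00492), the DNA damage sensor XPC at -1.97 ± 0.22 (adjusted p = 0.0135) and MLF2 at -1.92 ± 0.17 (adjusted p = 0.00492). Each of these 5 genes was read by 1 probe set, as were CXCL1, CXCL3, EFNA1 and IL6 among the higher genes, while TNFAIP3 was read by 2. Where a gene had several, 116 probe sets were lower by more than 1.5 in the BSA array than in the second control array, and the other probe sets of those genes had a median difference of 0.12. In all, the additive batch fit called 70 genes, 25 higher and 45 lower. Metal response genes averaged 0.49, all 8 higher (adjusted p = 0.0185, 6 passing when adjusted over the list alone), glucocorticoid targets 0.42, with 12 of 13 higher, and apoptosis regulators 0.31, with 23 of 24 higher (adjusted p = 0.0185 for either). None of these 3 held with an estimated correlation (adjusted p = 0.976). The median of all genes in the additive batch fit was 0.17, so part of these means and counts is a shift shared by all genes.

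The BSA calls depended on the batch term. Limma without it called 0 genes (587 at an unadjusted p under 0.05), and with it, at 1 residual degree of freedom, 53 (17 higher, 36 lower). There was 1 BSA array, so the carrier's own spread was not measured. The median gene was 0.19 higher in the BSA array than in the second control array. Without a batch term EFNA1 was at 2.12 ± 0.26, ZNF266 at -2.53 ± 0.30, LMAN2L, a lectin of the secretory pathway, at -1.77 ± 0.19 and the pseudogene UBBP2 at 1.21 ± 0.19, and the NF-kB list averaged 0.90 with 29 of 31 higher (adjusted p = 0.0167, and 0.885 with an estimated correlation). In that fit NFKBIZ was at 1.71 ± 0.27, IL6 at 0.57 (-1.55 to 2.68 with 1 control or E2-BSA array left out, at 0.94 in the BSA array), the growth factor gene CSF3 at 1.42 ± 0.45, NFKBIE at 1.23 ± 0.40 and TNFAIP2 at 0.87 ± 0.29. The interferon list averaged -0.29 with 5 of 28 higher (adjusted p = 1.0e-04, and 0.885 with an estimated correlation), MX1 at -0.86 ± 0.52, MX2 at -0.61 ± 0.60, SAMD9 at -0.58 ± 0.48 and IFI44L at 0.32 ± 0.27. Stress genes of the unfolded protein response averaged -0.20 with 10 of 30 higher (adjusted p = 0.00395) and hypoxia genes -0.21 with 7 of 24 higher (adjusted p = 0.00677), both at adjusted p = 0.885 with an estimated correlation. These falls average in the first control, of the set of 3. In BSA minus the second control, within the set of 8, none of these lists was lower: the median interferon-stimulated gene was at 0.27 (26 of 28 higher), the median unfolded protein gene at 0.27 (25 of 30) and the median hypoxia gene at 0.19 (20 of 24), where random lists of the same sizes had a median between 0.19 and 0.20. SAMD9 was at -0.16 there and at 0.0175 in the additive batch fit.

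**Figure D2:**
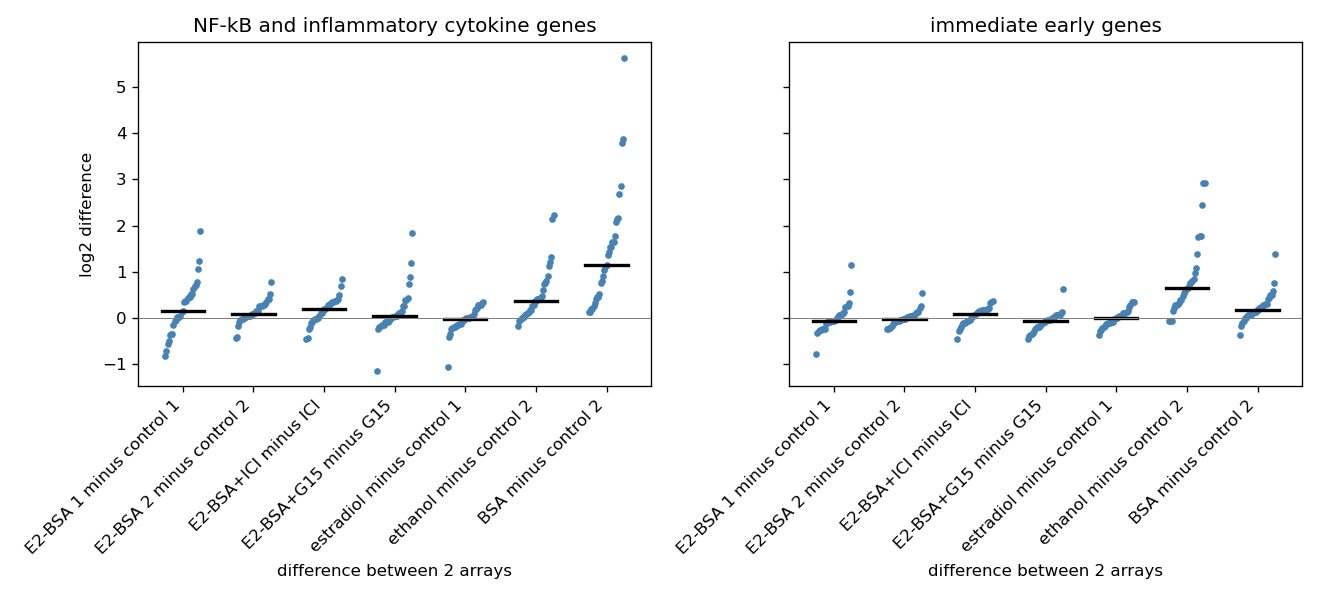
Log2 difference of each measured member of 2 gene lists in 7 differences between single arrays, with members as points in ascending order and the median as a bar. NF-kB and inflammatory cytokine genes were all above 0 in BSA minus control 2, with a median of 1.14, and immediate early genes stood apart in ethanol minus control 2, with a median of 0.65 and 27 of 30 higher.

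Against its own carrier, E2-BSA gave the opposite picture. In the additive batch fit the NF-kB and inflammatory cytokine genes averaged -1.31 ± 1.09 (SD over genes), with 0 of 31 members higher. CXCL1 fell by 4.56 ± 0.42 (SE, adjusted p = 0.00655), CXCL3 fell by 3.40 ± 0.32 (adjusted p = 0.00687), COXFA4L3 fell by 2.69 ± 0.36 (adjusted p = 0.0370), IL6 fell by 2.36 ± 0.14 (adjusted p = 0.00249) and TNFAIP3 fell by 2.20 ± 0.20 (adjusted p = 0.00655). Without a batch term IL6 was at -0.16 and COXFA4L3 at -0.81, with ranges of -2.38 to 2.06 and -2.55 to 0.92 when 1 control or E2-BSA array was left out. Higher were ZNF266 at 2.31 ± 0.14 (adjusted p = 0.00249), GPR137B at 2.02 ± 0.15, PPP1R15B at 1.98 ± 0.17, MLF2 at 1.84 ± 0.17 and the redox protein gene NXN at 1.82 ± 0.15 (adjusted p = 0.00655 for these 4), each read by 1 probe set. The fit called 61 genes, 41 higher and 20 lower, and of the NF-kB list 11 members passed over all genes and 21 when adjusted over the list alone (camera adjusted p = 4.4e-20). With an estimated correlation the list did not pass (adjusted p = 0.0514).

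Limma without a batch term called 0 genes between E2-BSA and BSA (438 at an unadjusted p under 0.05), and the batch term with 1 residual degree of freedom called 46. The smallest p without a batch term belonged to LMAN2L (1.86 ± 0.19), XPC (1.87 ± 0.23), EFNA1 (-1.99 ± 0.26) and NFKBIZ (-1.47 ± 0.27). TNFAIP2 was at -1.16 ± 0.29, NFKBIE at -1.27 ± 0.40 and CSF3 at -1.25 ± 0.45. In the additive batch fit metal response genes averaged -0.53 (0 of 8 higher, adjusted p = 0.00598), glucocorticoid targets -0.40 (0 of 13, adjusted p = 0.0395), apoptosis regulators -0.35 (0 of 24, adjusted p = 0.00392) and respiratory chain genes -0.29 (0 of 23, adjusted p = 0.0430), all at adjusted p = 0.965 with an estimated correlation. The median of all genes in that fit was -0.19, so part of these means and counts is a shift shared by all genes. Hypoxia genes averaged 0.26 without a batch term (18 of 24 higher, adjusted p = 0.0129, and 0.936 with an estimated correlation), a difference that crosses the sets of arrays. Within the set of 8 their median was 0.04 for E2-BSA minus the second control (random lists 0.02) and 0.19 for BSA minus that control (random lists 0.19), close to other genes in both. This comparison and that of BSA with control share the same BSA array.

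The vehicle, 0.1% ethanol, was set against the control, with 1 ethanol array whose own spread was not measured. Immediate early genes, which growth factors and stress induce within the hour, were higher in the ethanol array: in the additive batch fit they averaged 0.86 ± 0.84 (SD over genes) and 27 of 30 were higher. The transcription factor genes FOS and EGR1 rose by 3.04 ± 0.25 (SE, adjusted p = 0.0103) and 2.91 ± 0.17 (adjusted p = 0.00346). ARC rose by 2.51 ± 0.18 (adjusted p = 0.00661), TNFAIP3 by 2.36 ± 0.20 (adjusted p = 0.0103) and DDIT4, an inhibitor of mTOR signalling, by 2.34 ± 0.24 (adjusted p = 0.0243). EGR1 stood at 2.87 in the ethanol array and between -0.17 and 0.44 in the other 10. Of the list, 6 members passed over all genes and 19 when adjusted over the list alone (camera adjusted p = 4.6e-30), with adjusted p = 0.0552 for an estimated correlation. In the estradiol array, set against this vehicle below, the immediate early genes had a median of 0.0029 over the first control, with 15 of 30 higher.

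Other groups moved with them in the ethanol array. Genes reported after GPER activation averaged 0.82 (12 of 16 higher, adjusted p = 4.0e-10, and 0.0994 with an estimated correlation), and 11 of those 16 are in another list as well, EGR1 and FOS among them. NF-kB genes averaged 0.53 (25 of 31 higher, adjusted p = 1.2e-11) and hypoxia genes 0.45 (21 of 24 higher, adjusted p = 2.6e-11), both at adjusted p = 0.0552 with an estimated correlation. Unfolded protein and amino acid stress genes averaged 0.47 (22 of 30 higher, adjusted p = 2.8e-10, and 0.0994 with an estimated correlation). G2/M genes averaged -0.18 (5 of 25 higher, adjusted p = 2.5e-04, and 0.405 with an estimated correlation). The additive batch fit called 17 genes, all higher, the batch term with 1 residual degree of freedom 12, and limma without a batch term 0 (174 at an unadjusted p under 0.05). In the last fit EGR1 was at 2.97 ± 0.41, FOSB at 1.76 ± 0.27, JUNB at 1.59 ± 0.35, ARC at 2.41 ± 0.41, RGS2, a regulator of G protein signalling, at 1.82 ± 0.31, the phosphatase gene DUSP1 at 0.80 ± 0.19, C11orf96 at 1.67 ± 0.25, MICU3 at -0.91 ± 0.19 and FAM221A at -0.85 ± 0.19. The ethanol array also had the highest hybridisation controls, oligonucleotides and transcripts added at the hybridisation step, at 0.77 ± 0.21 (SD over 18 probe sets), where the other 10 arrays lay between -0.28 and 0.21.

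**Figure D3:**
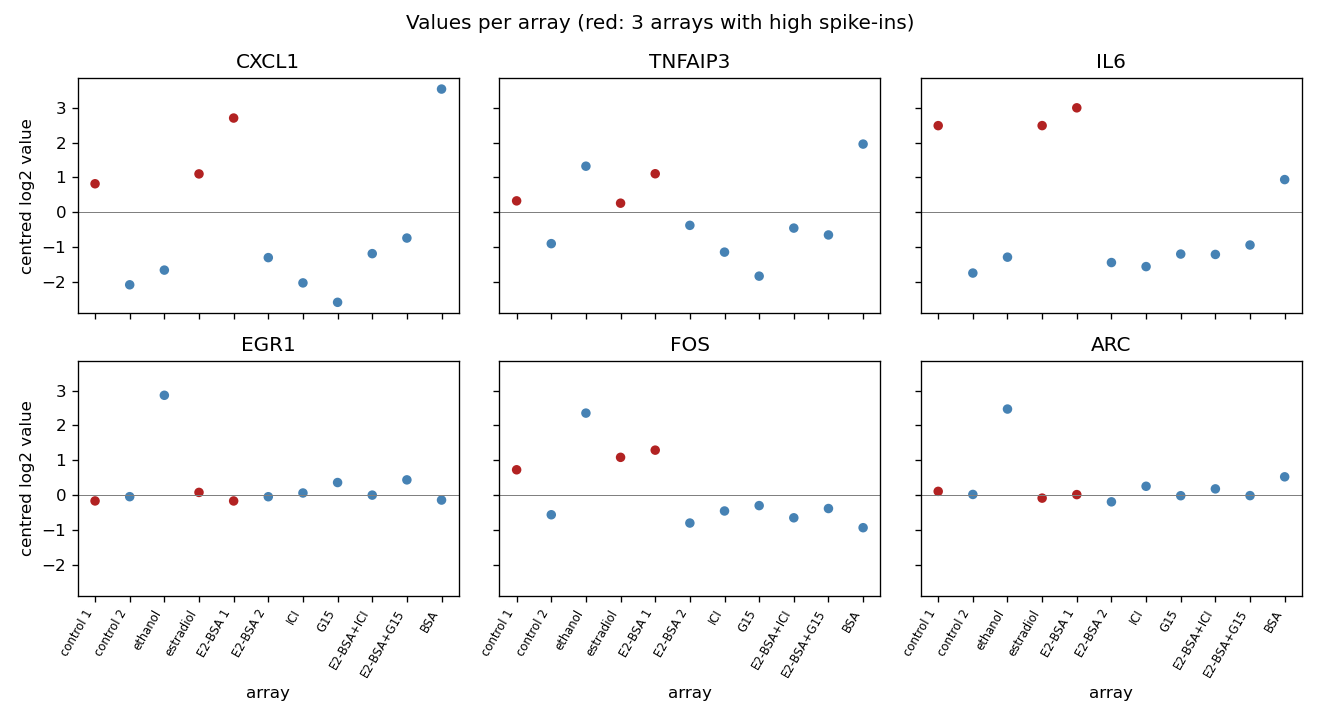
Centred log2 values of 6 genes in the 11 arrays, with the 3 arrays of high spike-in controls in red and the other 8 in blue. CXCL1 was highest in the BSA array at 3.54, EGR1 and ARC were highest in the ethanol array at 2.87 and 2.47, and IL6 lay between 2.49 and 3.00 in the 3 arrays of high spike-in controls.

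Free estradiol was set against its vehicle. In the additive batch fit camera called 9 of the 31 lists, 1 higher and 8 lower, and 0 with an estimated correlation. Immediate early genes were among those lower in the estradiol than in the ethanol array. In that fit they averaged -0.86 ± 0.85 (SD over genes), with 3 of 30 higher. ARC fell by 2.71 ± 0.24 (SE) and EGR1 fell by 2.67 ± 0.23 (adjusted p = 0.0378 for both), the 2 genes this fit called, and 19 members passed when adjusted over the list alone. Camera called the list lower (adjusted p = 8.5e-18), which was lost with an estimated correlation (adjusted p = 0.116). Within the set of 3 arrays, EGR1 differed by 0.25 and ARC by -0.19 between estradiol and the first control, and 15 of 30 immediate early genes were higher, with a median at the 59.1th percentile of random lists. Classical estrogen-induced genes averaged -0.10 against ethanol (9 of 27 higher, camera adjusted p = 0.513).

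Without a batch term limma called 0 genes between estradiol and ethanol (466 at an unadjusted p under 0.05), and with it, at 1 residual degree of freedom, 0 (1776). The estradiol and ethanol arrays lie in different sets, so 1 array on each side and the set were compared together in that fit. Its smallest p belonged to GPRASP1 (1.31 ± 0.25), FOXR2 (1.20 ± 0.24), CYP4Z2P (1.13 ± 0.23), MICU3 (1.07 ± 0.22) and TMEM170B (1.18 ± 0.25), and to EGR1 (-2.79 ± 0.47), FOSB (-1.75 ± 0.31), CSRNP1 (-1.68 ± 0.30), C11orf96 (-1.66 ± 0.29) and SP6 (-1.47 ± 0.24). ARC was at -2.56 ± 0.48, RGS2 at -1.51 ± 0.36, GADD45B at -1.17 ± 0.27, NFKBIZ at -1.28 ± 0.32 and DUSP1 at -0.90 ± 0.23. Interferon-stimulated genes averaged 0.78 with 24 of 28 higher (adjusted p = 8.3e-04, and 0.980 with an estimated correlation), MX2 at 1.48 ± 0.70 and MX1 at 1.13 ± 0.60. In the additive batch fit camera did not call that list, and between estradiol and the first control 5 of 28 were higher, with a median of -0.16.

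Free and conjugated estradiol were then compared at the same stated concentration, 1 µM, and the same time. The conjugate differs from the free hormone by its coupling to albumin, and the labels do not say whether its concentration counts hormone or conjugate. The effect of estradiol over ethanol lay below that of E2-BSA over control for immediate early genes, by a mean of -0.85 ± 0.90 (SD over genes) in the additive batch fit, with 5 of 30 higher. EGR1 differed by -2.67 (95% interval -3.25 to -2.09), ARC by -2.61 (-3.21 to -2.02), RGS2 by -1.90 (-2.60 to -1.20) and FOSB by -1.88 (-2.44 to -1.31), with intervals not adjusted for the number of genes. Camera called the list lower (adjusted p = 6.3e-16, and 0.135 with an estimated correlation), and 17 members passed when adjusted over the list alone. The rise of these genes lay in the ethanol array: EGR1 stood at 2.87 there and between -0.17 and 0.44 elsewhere, and the list median of ethanol minus the second control was 0.65. Estradiol minus the first control had a list median of 0.0029 (15 of 30 higher), with EGR1 at 0.25, so for these genes no difference between the hormones was shown apart from that of the vehicle array. For the receptors the difference was not resolved: PGR differed by -0.02 (-0.52 to 0.48), ESR1 by -0.26 (-0.73 to 0.21) and GPER1 by -0.15 (-0.61 to 0.32).

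No gene passed in that comparison of effects. Limma called 0 genes without a batch term (319 at an unadjusted p under 0.05), 0 with it at 1 residual degree of freedom (1854) and 0 in the additive batch fit (1669), where the lowest adjusted p was 0.0578, for TNFAIP3 at -3.21 ± 0.29 and EGR1. MICU3 was at 1.60 ± 0.27 and COX17, a copper chaperone, at 1.28 ± 0.27 without a batch term, and SP6 at -1.69 ± 0.29 and C11orf96 at -1.98 ± 0.36. The estradiol and E2-BSA arrays compared with each other, a comparison added after the data were seen, gave 0 genes without a batch term (293) and 0 in the additive batch fit (1539). There NF-kB genes averaged -0.24 in estradiol relative to E2-BSA, with 8 of 31 higher (camera adjusted p = 0.0019, and 0.610 with an estimated correlation), and classical estrogen-induced genes 0.04, with 17 of 27 higher (adjusted p = 0.767). Without a batch term interferon-stimulated genes averaged 0.63 (26 of 28 higher, adjusted p = 7.2e-06, and 0.951 with an estimated correlation), a difference that crosses the sets of arrays.

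The antagonists were compared in the presence and absence of E2-BSA. With ICI, LMNB1, which encodes a protein of the nuclear lamina, was at -1.21 ± 0.29 (SE), DENND4B at -0.91 ± 0.19, PPP1R14D at 0.77 ± 0.13 and the noncoding RNA PSLNR at 0.73 ± 0.11. With G15, TCF15 was at 0.92 ± 0.17, the signalling ligand gene WNT10B at 0.72 ± 0.13, RFXAP at -0.65 ± 0.15 and TAF2 at -0.59 ± 0.15. None of these passed. NF-kB genes averaged -0.48 with ICI (6 of 31 higher, adjusted p = 1.5e-06) and -0.54 with G15 (4 of 31 higher, adjusted p = 4.2e-07) without a batch term, and the calls were lost with an estimated correlation (adjusted p = 0.961 and 0.929). All 4 antagonist arrays lie in the set of 8, and with the additive batch term camera called 0 of the 31 lists for either antagonist. Against the second control, within the set of 8, the median NF-kB gene was at 0.13 in the ICI array (20 of 31 higher) and 0.08 in the G15 array (19 of 31 higher), where random lists had medians of 0.17 and 0.17, so the G15 value lay at their 1.56th percentile and the ICI value at their 17.4th. IL6 with ICI was at -1.96 ± 1.40 without and 0.21 with the batch term, and PTGS2, which encodes an inducible cyclooxygenase, at -1.43 ± 1.01 and 0.13.

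Limma without a batch term called 0 genes for ICI (2365 at an unadjusted p under 0.05) and 0 for G15 (1513). The additive batch fit called 0 for ICI (3219) and 0 for G15 (2042). With the batch term in the 8-array fit, ICI gave 12 lower genes without the G15 array and 4 lower genes without the E2-BSA+G15 array. The G15 term then rested on 1 array, so its gene counts are not given. Without the G15 array it rested on the E2-BSA+G15 array, in which 214 genes were lower by more than 1 than in the G15 array. With G15 and without a batch term, G1/S and DNA replication genes averaged 0.35 (19 of 22 higher) and G2/M genes 0.22 (22 of 25 higher), both called by camera (adjusted p = 0.0141) and lost with an estimated correlation (adjusted p = 0.929). The interferon list averaged -0.31 with ICI (5 of 28 higher, adjusted p = 5.3e-06, and 0.961 with an estimated correlation) and -0.30 with G15 (5 of 28 higher, adjusted p = 5.0e-04, and 0.929 with an estimated correlation), SAMD9 at -1.14 ± 0.38 and -0.79 ± 0.38. Within the set of 8 the list did not fall: against the second control its median was 0.18 in the ICI array and 0.15 in the G15 array, with 20 of 28 higher in either, where random lists had medians of 0.16 and 0.17, while SAMD9 was at -0.96 and -1.05.

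Whether an antagonist changes the response to E2-BSA was tested as the difference of the E2-BSA effects. With ICI, all 9 histone genes had a higher E2-BSA effect than without it, by a mean of 0.74 ± 0.45 (SD over genes), H2AC6 by 1.45 ± 0.81 (SE) and H2BC5 by 0.76 ± 0.41. Camera called that list (adjusted p = 1.7e-06), which was lost with an estimated correlation (adjusted p = 0.979). Without the first arrays of control and E2-BSA, which lie in the set of 3, the difference within the set of 8 averaged 0.37 over the list (8 of 9 higher), with H2AC6 at 0.50 and H2BC5 at 0.36. The antagonist arrays all lie in the set of 8. With G15, 7 of 9 histone genes had a higher effect (mean 0.64, adjusted p = 0.0019), and so did 22 of 28 interferon-stimulated genes (mean 0.27, adjusted p = 0.0019), both at adjusted p = 0.970 with an estimated correlation. Within the set of 8 the interferon difference averaged 0.0095 (14 of 28 higher) and the histone difference 0.27 (6 of 9 higher). The median of all genes was -0.08 in the G15 pair and 0.03 in the second E2-BSA pair. The interferon list lay at the 85.4th and 25.0th percentiles of random lists there. Whether a difference relative to other genes remained within the set of 8 was not tested. Limma without a batch term called 0 genes for ICI (33 at an unadjusted p under 0.05) and 0 for G15 (248), and the batch term with 1 residual degree of freedom called 0 for ICI (584) and 2 for G15. These were FAM111B, a protease gene, at -3.27 ± 0.24 and SRGAP2C, a human-specific copy of a gene with near-identical paralogs, at -2.68 ± 0.21 (adjusted p = 0.0375 for both). FAM111B stood at -2.43 in the E2-BSA+G15 array and between -0.60 and 0.96 in the other 10. On unchanged data simulated for that comparison, this fit made a mean of 0.1 to 17.2 false calls, depending on how the variances were drawn.

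The smallest p without a batch term in these tests belonged to COX17 (1.04 ± 0.27), TUBB7P (1.06 ± 0.32), RFPL3 (-1.31 ± 0.35) and LOC102724250 (-0.90 ± 0.25) for ICI. For G15 it belonged to SUPV3L1, a mitochondrial RNA helicase gene (1.79 ± 0.28), DPM3 (1.93 ± 0.31), the RNA helicase gene DHX9 (-1.71 ± 0.28) and ACBD3 (-1.45 ± 0.27). Across genes, which are not independent replicates, the E2-BSA effects without and with ICI had r = 0.079 (0.040 to 0.049 with 1 control or E2-BSA array left out), and those without and with G15 r = 0.018. The E2-BSA and estradiol effects had r = -0.103. The estradiol and ethanol arrays lie in different sets, so differences within the set of 8 give no chance range for that value. The absolute r of 15 disjoint pairs of differences between arrays without E2-BSA in the set of 8 lay between 0.00053 and 0.324, with a median of 0.044. Among those arrays ICI and G15 had r = 0.691 with each other, so that range need not be chance alone. The correlations for G15 and for estradiol changed sign with 1 control or E2-BSA array left out: that for G15 was -0.161 without the second control and -0.159 without the first E2-BSA array, and that for estradiol 0.651 without the first control and 0.554 without the second E2-BSA array. For estradiol, leaving out either of these arrays makes the sets unequal in the E2-BSA effect. The difference between the sets then enters both effects.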

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

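The tests of the 3 arrays that stand apart, those of the E2-BSA+G15 array and the splits with a batch term were chosen only after the result was seen, and an explanation of the former was reworded after its value was known. The other tests of the NF-kB list were laid down before their values were seen but after the list's shift had been. The check for a single distant sample in a group needs at least 4 samples, so it was not run.

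The poly-A spike-in controls, which no comparison tests but from which the batch term was drawn, averaged 1.62 in the first control, 1.58 in the estradiol and 1.40 in the first E2-BSA array, and at most 0.10 in the other 8, and 912 genes differed by more than 1 along the same division. By 1 measure the tables argue against an error of single probe sets as the whole cause: where a gene had more than 1 probe set, a pair of them had r = 0.317 in the lower of the 2 differences between the sets, above 0.266, the highest of the differences computed within the set of 8. As a part it is not excluded. Where 1 probe set was lower by more than 1.5, the other probe sets of its gene had medians of -0.31 between the control arrays and -0.28 between the E2-BSA arrays. Admixed cells of another type cannot be told apart from other causes, since the highest median of 4 marker lists, that of leukocyte markers (13 genes, 0 shared with another list), was 0.293, between the bounds of 0.2 and 0.5. The values are centred, so no levels of marker genes could be set beside it. Labelling, culture and another day of work stay open, and no biological explanation was tested, because each duplicated group has an array in either set.

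NF-kB and inflammatory cytokine genes were higher with E2-BSA, by a mean of 0.17, with medians of 0.17, 0.10, 0.19 and 0.04 in the 4 array pairs. Both technical explanations stay open: over the 31 members, the 3 E2-BSA pairs that share no array with the second control had r = 0.739 with BSA minus that control (random lists reached 0.405 at their 95th percentile) and r = 0.513 with ethanol minus that control (0.407), so the shift could come from the carrier protein or from a response to handling. Chance was not excluded, but the splits are a weak test of it. With a term for the sets in every fit, 32 splits of the 8 arrays could be fitted. Of these, the real one included, 7 gave as large a list shift (real 0.17, highest other 0.19). As many genes at an unadjusted p under 0.05 came from 18 of 32 (real 924, highest other 2414). Without that term the counts were 25 of 34 (highest other 1.16) and 23 of 34 (real 208, highest other 7371), but splits that put the first control and first E2-BSA array on the same side carry the difference between the sets: with both ICI or both G15 arrays beside them, the same model in either case, 4959 genes were called. With a term for the sets, each other split with a list shift as large had a partner split that gave the same fit, so those counts hold repeats. Each of them also compared some pairs in their real direction and left out the others, so they do not measure chance for the list shift. Among the splits that part all 4 pairs, the real one had the largest list shift and the next had 0.10. Such splits are too few to exclude chance. An action of the conjugated hormone itself stays open too, as untested.

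The E2-BSA effect differed with and without G15, by a test of that difference with a batch term, for FAM111B (-3.27) and SRGAP2C (-2.68). Both rest on the E2-BSA+G15 array, in which 214 genes were lower by more than 1 than in the G15 array and 52 higher. Its 18S control averaged -1.65, where the other 10 arrays lay between -0.28 and 0.35. Its 3 prime minus 5 prime differences of GAPDH and ACTB gave no sign of degraded RNA. They lay below the highest of the other 10 arrays, the closer by -0.234. Most arrays would do so, and only 2 transcripts were read, so degradation is not excluded. FAM111B averaged 2 probe sets and stood at -2.43 in that array. The lowest value of any probe set was -4.20, so both of its probe sets lay below their own medians there. An error of single probe sets stays open for SRGAP2C, read by 1 probe set, and for the array as a whole. There 687 probe sets were lower by more than 1.5, and the other probe sets of their genes had a median of -0.21. An interaction of G15 with E2-BSA stays open as well, with 1 array to rest on.

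The hybridisation controls, which none of the comparisons uses, averaged 0.77 in the ethanol array, where the others lay between -0.28 and 0.21.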

How the results depend on the processing

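The tests with a batch term, with median centring and with every probe set singly were chosen only after the data were seen. Without a batch term the count of genes was 0 in all 11 comparisons, and it stayed 0 with quantile normalization, median centring, no trend, every probe set tested singly and each control and E2-BSA duplicate left out in turn. For E2-BSA, ICI and G15 present against absent each of the 8 arrays was left out. The ethanol, estradiol and BSA arrays, the only ones of their groups, were not. Such a fit recovered few simulated changes, so these zeros say little about stability. For E2-BSA against control the count was 0 with the 4 arrays alone (74 at an unadjusted p under 0.05) and with the replicate number as a block (1117, against 62 without). The labels mark the second arrays by number only and do not say that equal numbers were handled together, and the block coincides with the division by spike-ins. For E2-BSA present against absent it was 0 without antagonist terms (171) and with the BSA array added (237), and for the effect difference 0 with the BSA array as control (343).

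The batch term changed the counts. With it, with it and no trend, and in the additive batch fit, the counts were 46, 49 and 61 for E2-BSA against BSA, 53, 56 and 70 for BSA against control, and 12, 15 and 17 for ethanol against control. Estradiol against ethanol gave 2 genes with a batch term and no trend and 2 in the additive batch fit, and the G15 interaction gave 2 with a batch term, with or without the trend. With the batch term and without the G15 array ICI gave 12 lower genes and G15 170 (1 higher, 169 lower), and without the E2-BSA+G15 array 4 and 1, all lower. The batch term removes the difference between the sets from the spread, and for the arrays left out the cause was not tested.

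Lists passing fell to 0 with an estimated correlation in each of the 11 comparisons without a batch term. Quantile normalization gave 2 for E2-BSA against control (4 without it), 1 for E2-BSA present (3), 1 for BSA against control (4), 3 for G15 (8) and 1 for the G15 interaction (2). Median centring gave 2 for E2-BSA against control. With the batch term the lists passing were 7 for E2-BSA against control, 5 for E2-BSA against BSA, 9 for ethanol, 9 for estradiol against ethanol, 11 for the effect difference, 0 for ICI, 0 for G15 and 2 for the ICI interaction. In the additive batch fit they were 5 for E2-BSA against BSA, 10 for ethanol, 9 for estradiol against ethanol, 9 for the effect difference, 0 for ICI and 0 for G15. The cause of the changes with quantile normalization and centring was not tested.

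Single genes changed sign in these cases. In the additive batch fit SAMD9 was at 0.038 for E2-BSA against control and 0.018 for BSA against control. For E2-BSA present, ESRRG was at 0.014 with quantile normalization, and ESRRA and NR3C1 at -0.014 each with the BSA array added. NFKBIZ was at 0.19 for the effect difference with the BSA array as control. With a batch term, H2BC5 was at 0.017, NR3C1 at -0.0030 and ESRRG at 0.068 for E2-BSA present without the first control or the first E2-BSA array, ESR2 at -0.037 without the ICI or E2-BSA+ICI array, and ESRRG at 0.048 without the G15 or E2-BSA+G15 array. For ICI, PTGS2 was at 0.13 and IL6 at 0.21 with a batch term, with it and no trend, in the additive batch fit, and with it without the first control, first E2-BSA, G15 or E2-BSA+G15 array. They were at 0.20 and 0.24 without the second control, 0.050 and 0.17 without the second E2-BSA array, 0.12 and 0.20 without the ICI array, and 0.13 and 0.21 without the E2-BSA+ICI array. IL24 was at 0.0071 and IRF7 at -0.015 without the second control, and IL24 at 0.075 without the E2-BSA+ICI array. For G15 with a batch term, MX2 was at 0.036 without the second E2-BSA array, and IL11 at -0.028 and SAMD9 at 0.17 without the G15 array.

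With 1 of the 4 control and E2-BSA arrays left out and no batch term, ISG15 for E2-BSA against control ranged from -0.70 to 0.022. With 1 of the 8 arrays left out, PGR for E2-BSA present ranged from -0.19 to 0.016, GPER1 from -0.17 to 0.053, ESRRG from -0.14 to 0.085 and ESR2 from -0.037 to 0.040. With 1 of the 4 arrays left out again, COXFA4L3 for E2-BSA against BSA ranged from -2.55 to 0.92, IL6 from -2.38 to 2.06, IL6 for BSA against control from -1.55 to 2.68 and MX2 from -1.33 to 0.11. The correlation of the E2-BSA effects without and with ICI ranged from 0.040 to 0.049, that with G15 from -0.161 to 0.217, and that of the E2-BSA and estradiol effects from -0.739 to 0.651. Leaving out a control or E2-BSA array changes how the sets are spread over the sides, so the difference between the sets can enter those values. Beyond that the cause was not tested.

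Of the other values of single genes, 194 kept sign and side of the threshold with median centring, 194 without the trend and 193 with quantile normalization. In the additive batch fit 128 did so and 40 passed that had not. Alternatives not run were a stricter filter on dim genes, other pseudocounts and the brightest probe set, since centred values leave no level to choose by, and no filter was already in use. Signal over background is not known for these values, so its limit on any gene cannot be given.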

Other observations

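The tests with a batch term, the comparison of estradiol with control and the comparisons between the sets of 3 and 8 arrays were chosen only after the data were seen.

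Several gene groups followed the division by spike-ins. With the control and E2-BSA duplicates averaged within each set, the median NF-kB and inflammatory cytokine gene was 0.86 higher in the set of 3 than in the set of 8 (28 of 31 higher), and the median interferon-stimulated gene 0.85 higher (27 of 28 higher), both above all of 10000 random lists. So were hypoxia genes at 0.75 (21 of 24 higher), unfolded protein and amino acid stress genes at 0.69 (26 of 30), genes reported after GPER activation at 0.56 (13 of 16) and ERK feedback targets at 0.47 (16 of 20). G1/S and DNA replication genes lay below all random lists, with a median of -0.58 and 5 of 22 higher, and G2/M genes had a median of -0.29, with 3 of 25 higher. IL6 differed by 4.34 and CXCL1 by 3.46.

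Free estradiol, compared with the control of its own set, had few large differences: 20 genes were higher by more than 1 and 24 lower, where the first E2-BSA array had 26 and 75. The median histone gene was at -0.51 (1 of 9 higher) and the median interferon-stimulated gene at -0.16. Both differences subtract the first control array, as that of the first E2-BSA array does, and H2AC6 stood at 1.10 in that control, so they are no independent evidence of a shared response. Limma called 0 genes between estradiol and control without a batch term (269 at an unadjusted p under 0.05) and 0 in the additive batch fit (1397), and classical estrogen-induced genes averaged -0.02 there, with 12 of 27 higher.

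Between array pairs that share no array, E2-BSA differences had r = 0.0999 for the first and second arrays of the groups, over 19775 genes that are not independent replicates. That was the highest of 6 such correlations, and the other 5 lay between -0.0194 and 0.0744. In the second pair, E2-BSA minus control within the set of 8, 0 genes differed by more than 1 in either direction.

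Over all 4 E2-BSA pairs, 2 genes, CXCL1 and TNFAIP3, named after their values were seen, were higher by more than 0.5 in each pair, and 0 were lower by more than 0.5 in each.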
